A study of Mus musculus with 7 samples.

How the data were processed

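Gene expression was measured by 1-colour microarray in mouse CD8 T cells from lymph node. The cells carried the OT-1 T cell receptor transgene, which recognises the ovalbumin peptide SIINFEKL, on a Rag-/- background. Per the labels' protocols, lymphocytes were cultured with 100 nM SIINFEKL for 24 h, total RNA with an integrity number above 8 was kept, and 50 ng was labelled with Cy3. There were 4 WT and 3 Lck-/- samples, stated by the series to be biological replicates. In the Lck-/- samples an inducible Lck had been switched off by 7 days without dietary doxycycline. No doxycycline feeding or withdrawal is given for the WT samples. If the groups differed in feeding or in the inducible construct, this cannot be told apart from loss of Lck. Groups and replicate numbers came from the sample titles.

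Each array held 62976 features, of which 59305 were non-control spots of 55681 probes. Per the file headers, the scanner files were made with Agilent Feature Extraction 10.7.3.1 and give spot intensity. Per the file headers, spatial and multiplicative detrending and surrogate values for dim spots were on, and the background subtracted from the processed intensity was the fitted spatial surface. Intensities had not been brought to a common scale between arrays, since the 75th percentile of the processed signal ran from 353.6 to 615.4. The authors' deposited value table holds log2 values keyed by feature number. Its columns correlated at 0.9994 to 0.9998 with log2 of the spot median signal of the same array, and their medians ran from 6.57 to 6.61. The kind of between-array normalization behind it is not given in the sources used here. The submitters' processing notes name limma without a version or role. That table was used only as an alternative.

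The values reported are log2 of the processed signal minus each array's 75th percentile of it over non-control spots. A value of 0 is therefore the 75th percentile of that array. Spots flagged as outliers were left out and the remaining spots of a probe were averaged. A probe entered when it was well above background on at least 3 of the 7 arrays. Of the 55681 probes, 36686 had a gene name. The reference gene table, of assembly GRCm38.p6 and used for names only, named 27229 of them by accession, 3581 by symbol and 565 by synonym, and 5311 kept the name in the files. Another 18995 probes, named only by an ID or a lincRNA interval, were left out. A gene was represented by its probe with the highest mean over all 7 arrays, a choice that mattered for 4281 genes with more than 1 passing probe. This left 16452 genes, of which 771 lacked at least 1 outlier-flagged value. Probe coordinates are those of the files, on mm9. The exon or untranslated region under a probe was not analysed here.

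The arrays labelled Lck-/- were compared with the arrays labelled WT with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment, threshold 0.05). Differences are Lck-/- minus WT on the log2 scale. The 22 gene lists, holding 519 distinct genes of which 461 were tested, were written from general knowledge before the data were examined. Lists were tested with camera at its preset correlation of 0.01, with camera at an estimated correlation and with fry, over the 15681 genes with a value on every array. A list member that is named with a missing value was therefore not part of these tests. Camera compares a list with the other genes. The directional test of fry asks whether the genes of a list move on balance in 1 direction, and its mixed test whether they change in either direction. The rule for naming genes was also fixed before the data were examined. It took 20 genes of T cell signalling and effector function (1 of them is not reported here), the largest changes past the threshold (there were none), and from each list up to 4 members past the threshold or else the 2 members with the highest mean signal. Any other gene named was chosen after its values were seen. Where no array of a group was well above background, a fold is given as a lower bound, from the bright group's mean against the mean, per array, of the higher of the dim probe's own value and the lowest value among probes well above background.

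All 7 arrays were on 1 slide with 1 scan setting, so neither slide nor scan could part the groups. Arrays with the same title number did not deviate together, so the numbers were not taken to pair the samples. The alternatives tried were quantile normalization, normexp with an offset of 50 followed by quantile normalization, median centring, the deposited table, 2 other background filters, the mean of a gene's probes, the title number, the number in the file names or the slide row as a block, array weights, a robust variance trend, and leaving out each array. After the data were seen, 2 alternatives were added: leaving out both arrays whose Lck signal went against their label, and using the mean NK marker signal as a covariate.

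The procedure was tested on simulated data for the 15681 genes, with independent noise of each gene's own spread. For the comparison of 4 with 3 arrays it recovered 50 of 100 genes changed 2-fold and 79 of 100 changed 4-fold, with 5 calls among 15481 unchanged genes. Figures were drawn with matplotlib 3.10.9. The number of arrays limits the precision of every value.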

Results

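The series asked how loss of the kinase Lck alters the transcriptome of antigen-activated CD8 T cells. Lck phosphorylates the CD3 and zeta chains when the T cell receptor is engaged. All 7 samples were OT-1 CD8 T cells taken 24 h after activation with 100 nM SIINFEKL peptide, 4 labelled WT and 3 labelled Lck-/-. Between 46.57% and 61.06% of spots were well above background on each array, the lowest on the array labelled WT 1 and the highest on the array labelled Lck-/- 1, and no spot was saturated. Spots marked as non-uniform outliers numbered 1403 on the array labelled WT 3, 422 on Lck-/- 1 and 144 on Lck-/- 3, against 1 to 31 on the others. Arrays correlated at 0.98 to 0.992 across genes. The highest correlation joined the arrays labelled WT 4 and Lck-/- 2, from different groups, while pairs of WT arrays reached 0.985 to 0.987 and pairs of Lck-/- arrays 0.983 to 0.99.

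Lck signal did not part the groups as labelled. The only Lck probe (A_55_P2155504, mm9 chromosome 4, 129225614 to 129225673) read 7.12 ± 0.74 (SD, n = 4) on the arrays labelled WT and 6.80 ± 1.06 (SD, n = 3) on those labelled Lck-/-, a difference of -0.32 (SE 0.55, limma adjusted p = 0.954). With both arrays that go against their label left out it was -1.29, without Lck-/- 1 -0.93, without WT 4 -0.68, and between -0.25 and -0.01 without any other array, none past the threshold. With the NK marker mean as a covariate it was 0.34 (SE 0.48). The array labelled Lck-/- 1 had the highest signal of all, 8.02, above the 7.44, 7.67 and 7.36 of the arrays labelled WT 1, WT 2 and WT 3. The array labelled WT 4 had the lowest, 6.04, next to 6.21 and 6.17 on the arrays labelled Lck-/- 2 and Lck-/- 3. All values were well above background. The labels do not say which part of Lck the knockout removes, so this probe may lie outside it and then checks nothing. Whether the probe also reads the inducible Lck, and how far that was switched off in each Lck-/- sample, was not tested. Every direction given from here on is between arrays as labelled.

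**Figure D1:**
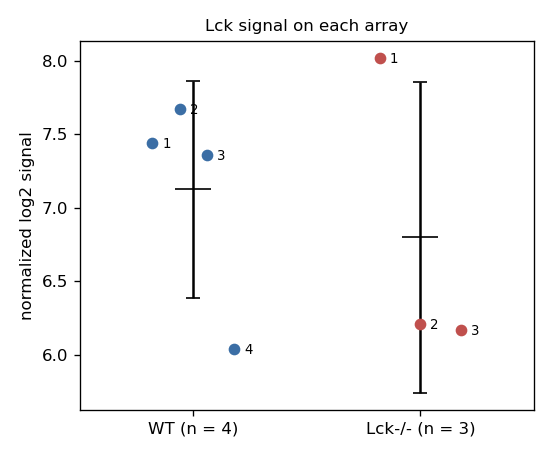
Normalized log2 signal of the Lck probe on each array (vertical axis, relative to the array's 75th percentile) for the arrays labelled WT (n = 4) and Lck-/- (n = 3). Points are arrays with their replicate numbers, bars the group mean and SD. The array labelled WT 4, at 6.04, sits with Lck-/- 2 and 3, and the array labelled Lck-/- 1, at 8.02, sits above all WT arrays.

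No gene passed the threshold between the arrays labelled Lck-/- and WT. Of 16452 genes tested with limma, 0 were higher and 0 lower at an adjusted p under 0.05, so 0 changed at least 2-fold. At an unadjusted p under 0.05 there were 1160 genes, against about 823 by chance. Among the 35 splits of the arrays into groups of these sizes, this count ranked 7, with counts from 249 to 2311. Chance therefore cannot be excluded for this excess. Of the 1160 genes, 827 were higher and 333 lower with the 75th percentile as reference. With the median as reference, which moved the median of all differences by -0.2, 236 were higher and 772 lower. The share that was higher, 71.3%, became 57.1% with quantile normalization, 56.6% with normexp, 49.4% with the deposited values and 23.4% with the median as reference. Without the array labelled Lck-/- 3 there were 744 such genes. The groups did not overlap for 7.3% of genes, where chance gives 5.7% on average. Without the array labelled WT 1 the only call was Xist. With both arrays whose Lck signal went against their label left out, 34 genes were higher and 22 lower. Those arrays were picked by their signal, and the arrays left are parted as in the split with 79 calls described below. These calls are therefore not independent of that split.

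The genes with the smallest p-values were chosen after their values were seen. Timd2, which encodes a T cell immunoglobulin and mucin domain protein, came closest to the threshold (adjusted p = 0.07). It was well above background on all 4 arrays labelled WT and not well above background on the 3 labelled Lck-/-, at least 2.42-fold lower there. Of the 12 genes with the next smallest p-values that were above background on all 7 arrays, leaving out predicted and uncharacterised genes, 5 with a known role in T cells follow, and the others were Idi2, Cul9, S100a1, Kremen2, Slc6a19, H2-DMa and Uaca. The inhibitory ligand Cd200 read 4.70 ± 0.34 (SD, n = 4) in WT and 2.92 ± 0.52 (SD, n = 3) in Lck-/-, a difference of -1.78 (SE 0.28). The T-box transcription factor Eomes went the other way, from 0.28 ± 0.55 (SD, n = 4) to 2.20 ± 0.60 (SD, n = 3), a difference of 1.93 (SE 0.36). Differences were -1.37 (SE 0.26) for the MAP kinase phosphatase Dusp4, -0.95 (SE 0.15) for the G protein regulator Rgs1 and 0.72 (SE 0.14) for the survival factor Bcl2. None of these 5 passed over all genes (limma adjusted p = 0.592 for each), although each parted the 4 arrays labelled WT from the 3 labelled Lck-/- without overlap.

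Genes of mitosis were lower on the arrays labelled Lck-/-. All 23 tested members of the list of G2 and mitosis genes had a negative difference, with a median of -1.04 (quartiles -1.30 and -0.89), or 2.06-fold. The list was called by camera at its preset correlation (adjusted p = 2.08e-20). It was not called with an estimated correlation (adjusted p = 0.844) or by fry's directional test (adjusted p = 0.576). The estimated correlation between its genes was 0.92, far above the preset 0.01, so the preset p-value is likely too small. The NK markers, with an estimated correlation of 0.86, were higher as a list at the preset correlation of camera. They were not called with the estimated one (adjusted p = 0.845). They tended to be high on the arrays where the mitosis genes were low. With the NK mean as a covariate the median of the mitosis list was -0.59, and with both doubted arrays out it was -1.57. No member passed over all genes or adjusted over the list alone, while 15 lay below an unadjusted p of 0.05. The proliferation marker Mki67 read 5.22 ± 0.84 (SD, n = 4) and 3.77 ± 0.79 (SD, n = 3), a difference of -1.45 (SE 0.51). The chromosomal passenger genes Birc5 and Cdca8 both differed by -0.89 (SE 0.37 and 0.39). Relative to the WT mean, the list mean was 0.86, -0.62, 0.45 and -0.69 on the arrays labelled WT 1 to WT 4 and -0.53, -1.41 and -1.47 on those labelled Lck-/- 1 to Lck-/- 3.

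DNA replication and cholesterol synthesis genes were lower as lists at the preset correlation of camera. Of the 29 replication and S phase genes, 23 had negative differences, with a median of -0.15 (camera adjusted p = 4.84e-05, and adjusted p = 0.844 with an estimated correlation). Of 23 cholesterol synthesis genes, 21 had negative differences, with a median of -0.26 (camera adjusted p = 1.51e-05, and adjusted p = 0.844 with an estimated correlation). No member of either list passed over all genes or adjusted over the list alone. The replicative helicase genes Mcm6 and Mcm3 differed by -0.03 (SE 0.17) and 0.07 (SE 0.23), and the sterol pathway genes Fdps and Ebp by -0.06 (SE 0.49) and -0.21 (SE 0.14). Relative to the WT mean, the replication mean was 0.15, -0.30 and -0.33 and the cholesterol mean 0.26, -0.48 and -0.54 on the arrays labelled Lck-/- 1 to Lck-/- 3. The replication median was -0.31 without Lck-/- 1, -0.08 without Lck-/- 2, -0.05 without Lck-/- 3 and -0.10 without WT 1. The cholesterol median was -0.53, -0.13 and -0.16 without Lck-/- 1, Lck-/- 2 and Lck-/- 3. With both doubted arrays out the medians were -0.31 and -0.54, and with the median as reference -0.36 and -0.46. With the NK marker mean as a covariate they were -0.08 and -0.15 and neither list was called (adjusted p = 0.167 for each, the highest of 21 settings, where the lowest were 7.44e-11 and 2e-13).

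Cytotoxic granule genes were higher as a list on the arrays labelled Lck-/-. Of 17 members, 13 had positive differences, with a median of 0.14, which was -0.06 with the median as reference (camera adjusted p = 0.043, and adjusted p = 0.844 with an estimated correlation). The protease gene Gzmb read 6.14 ± 1.12 (SD, n = 4) and 8.00 ± 0.26 (SD, n = 3), a difference of 1.86 (SE 0.55, limma adjusted p = 0.637). The pore-forming Prf1 differed by 0.01 (SE 0.17) and the proteoglycan Srgn by -0.14 (SE 0.26). No member passed over all genes, and 1 passed adjusted over the list alone, Ctsw, a cathepsin of cytotoxic cells, at 0.85 (SE 0.20). Markers of NK cells, which share granule genes with CD8 T cells, were higher too, all 10 with positive differences and a median of 1.29 (camera adjusted p = 0.00587, and adjusted p = 0.845 with an estimated correlation). No NK marker passed over all genes or adjusted over the list alone, and the most abundant, the adaptor Tyrobp and the receptor Klra8, differed by 0.95 (SE 0.62) and 1.56 (SE 0.86). The NK marker mean was 1.84 above the WT mean on the array labelled WT 4 and 2.31 above it on the array labelled Lck-/- 2, against -0.82 to 0.71 on the other 5 arrays. The NK median was 0.48 with the deposited values, 0.49 with normexp, 0.74 without Lck-/- 2 and 2.24 with both doubted arrays out. The cytotoxic median was 0.07 without Lck-/- 2, 0.09 without WT 3, 0.22 without WT 2 and 0.23 without Lck-/- 3. With the NK mean as a covariate it was 0.05 and the list was not called (adjusted p = 0.41, the highest of 21 settings, where the lowest was 0.00427), nor with array weights (0.0618). Without the array labelled Lck-/- 2 neither list was called (adjusted p = 0.406 and 0.357), nor without WT 1 (0.056 and 0.0567), and the cytotoxic list was not called without WT 3 (0.0824).

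**Figure D2:**
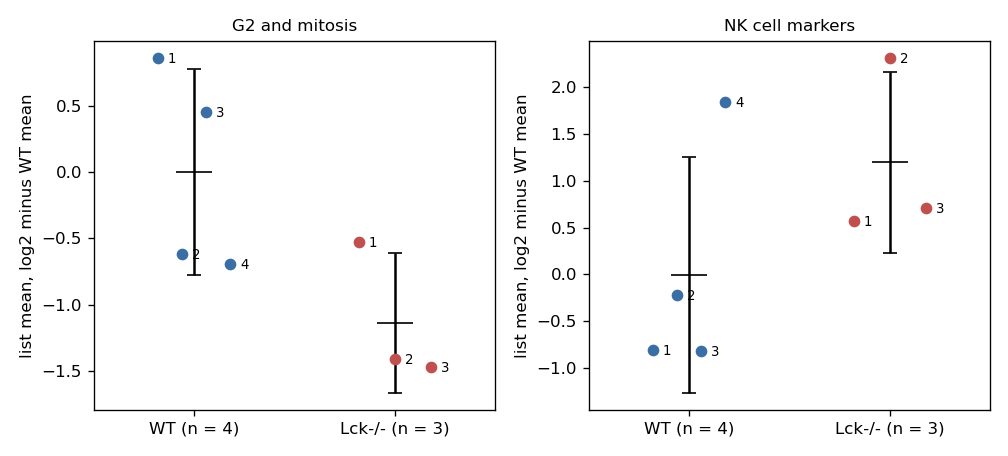
Mean normalized log2 signal of the G2 and mitosis list (left) and of the NK cell marker list (right) on each array, relative to the WT mean (vertical axes), for the arrays labelled WT (n = 4) and Lck-/- (n = 3). Points are arrays with replicate numbers, bars the group mean and SD. G2 and mitosis values are lowest on Lck-/- 2 and 3, at -1.41 and -1.47, and NK marker values are highest on WT 4 and Lck-/- 2, at 1.84 and 2.31.

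Surface receptors and feedback regulators of activated T cells were lower as lists, with members in both directions. Of 23 activation-induced receptors, 14 had negative differences, with a median of -0.17 (camera adjusted p = 0.0099, and adjusted p = 0.844 with an estimated correlation). Only Cd200 passed adjusted over the list alone, and 0 passed over all genes. The interleukin 2 receptor chain Il2ra differed by -0.33 (SE 0.17), the early activation marker Cd69 by 0.09 (SE 0.31) and the costimulatory receptor Tnfrsf18 by 0.06 (SE 0.24, with 2 Lck-/- values). The receptor median was -0.05 without WT 1, -0.09 without Lck-/- 3, -0.06 without Lck-/- 1 and -0.07 with both doubted arrays out, and -0.37 with the median as reference. Without Lck-/- 1 the list was not called (adjusted p = 0.13), nor with both doubted arrays out (0.229, the highest of 21 settings, where the lowest was 0.00198). Of 25 feedback regulators, 16 had negative differences, with a median of -0.15 (camera adjusted p = 0.043, and adjusted p = 0.85 with an estimated correlation). Adjusted over the list alone 4 changed: Dusp4 and Rgs1 fell, while Socs1 and Socs3, which restrain cytokine signalling, rose by 0.72 (SE 0.18) and 0.82 (SE 0.21). None passed over all genes. Fry's mixed test, which asks for change in either direction, called this list (adjusted p = 0.00662). The inhibitory receptors Cd6 and Cd5 differed by -0.31 (SE 0.23) and -0.41 (SE 0.41). The feedback median was -0.05 without WT 2, -0.10 without WT 4, -0.04, -0.28 and -0.05 without Lck-/- 1, Lck-/- 2 and Lck-/- 3, and 0.05 with both doubted arrays out. With the median as reference it was -0.35. The camera call of this list was made in 8 of 21 settings (adjusted p from 0.0157 to 0.318). It was lost without WT 2, WT 4 or Lck-/- 1 (0.184, 0.0537 and 0.198), without both doubted arrays (0.23), and with quantile normalization (0.0851), median centring (0.101) or the deposited table (0.113).

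Transcription factors and cytokines induced through the receptor were not called as lists. Of 25 transcription factors, 13 had positive differences, with a median of 0.04, or -0.16 with the median as reference (camera adjusted p = 0.93), and only Eomes passed adjusted over the list alone. The factor median was -0.06 without Lck-/- 2, 0.01 without WT 3 and 0.08 without Lck-/- 1 or Lck-/- 3. Irf8 and Irf4, interferon regulatory factors, differed by 0.75 (SE 0.22) and -0.30 (SE 0.20), Myc, a driver of growth, by 0.22 (SE 0.19) and Tbx21, which encodes T-bet, by 0.19 (SE 0.21). Of 23 cytokine and chemokine genes, 14 had positive differences, with a median of 0.10, or -0.10 with the median as reference (camera adjusted p = 0.762), and none passed adjusted over the list alone. The cytokine median was 0.34 without Lck-/- 1, 0.25 without WT 2, 0.17 without WT 4, 0.06 without WT 1, 0.04 without Lck-/- 2 or Lck-/- 3 and -0.03 without WT 3. With both doubted arrays out it was 0.51, and with the NK marker mean as a covariate -0.18. This list was called, upward, without the array labelled Lck-/- 1 (adjusted p = 0.0152), without both doubted arrays (0.000814) and with the title number as a block (0.0458), within 0.000814 to 0.947 over 21 settings. The growth factor Il2 read 3.96 ± 0.76 (SD, n = 4) and 2.92 ± 0.62 (SD, n = 3), a difference of -1.04 (SE 0.45, limma adjusted p = 0.699). The effector cytokines Ifng and Tnf differed by 0.56 (SE 0.59) and 0.64 (SE 0.43), the chemokine Ccl4 by -0.07 (SE 0.44) and lymphotoxin beta, Ltb, by 0.42 (SE 0.18).

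Genes of naive cells and of proximal receptor signalling were not called either. Of 27 naive and quiescence genes, 19 had positive differences, with a median of 0.20, or 0.00 with the median as reference (camera adjusted p = 0.106), and only Bcl2 passed adjusted over the list alone. It was called in 8 of 21 settings (adjusted p from 0.0152 to 0.634), among them without WT 2 (0.0382) or Lck-/- 1 (0.0152), with quantile normalization (0.0423) and with the deposited table (0.0213). The naive median was 0.11 without WT 3 and with the NK marker mean as a covariate, and 0.12 without Lck-/- 2. The lymph node homing receptor Ccr7 differed by 0.47 (SE 0.21), the surface antigen gene Ly6c1 by 0.50 (SE 0.16) and the interleukin 7 receptor Il7r by 0.08 (SE 0.26). Of 34 proximal signalling genes, 23 had positive differences, with a median of 0.10, or -0.10 with the median as reference (camera adjusted p = 0.198), and none passed adjusted over the list alone. It was called in 3 of 21 settings (adjusted p from 0.0131 to 0.749), among them normexp (0.0321) and the deposited table (0.0131). The proximal median was 0.02 without WT 3, 0.15 without WT 1, 0.16 without WT 4 or both doubted arrays and 0.05 with the NK covariate. The kinases Fyn and Zap70 differed by -0.02 (SE 0.16) and -0.11 (SE 0.18). The receptor components Cd3d and Cd3e differed by 0.06 (SE 0.15) and 0.21 (SE 0.39, with 3 WT values), and the coreceptor Cd8a by 0.38 (SE 0.25).

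**Figure D3:**
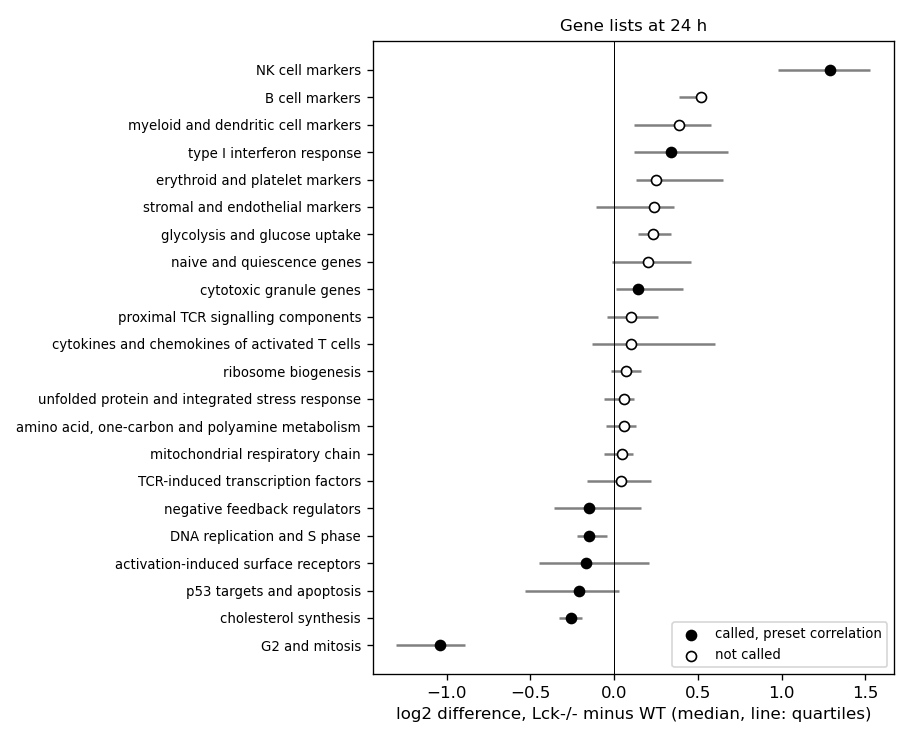
Median log2 difference between the arrays labelled Lck-/- (n = 3) and WT (n = 4) of each gene list (horizontal axis), with lines for the quartiles over its members. Filled points are lists called by camera at its preset correlation. The list of G2 and mitosis genes lies lowest, at -1.04, and the NK cell markers highest, at 1.29.

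Interferon response genes were higher and p53 target genes lower as lists. Of 28 interferon genes, 24 had positive differences, with a median of 0.34 (camera adjusted p = 0.0117, and adjusted p = 0.85 with an estimated correlation). Bst2 and Isg15, antiviral genes, differed by 0.31 (SE 0.17) and 0.25 (SE 0.29). Relative to the WT mean, the list mean was -0.35 on the array labelled Lck-/- 1 and 0.88 and 0.68 on those labelled Lck-/- 2 and Lck-/- 3. The median was 0.70 without Lck-/- 1, 0.20 without Lck-/- 2, 0.78 with both doubted arrays out, 0.13 with the median as reference and 0.09 with the NK marker mean as a covariate. The call was lost without WT 2, Lck-/- 2 or Lck-/- 3 (adjusted p = 0.0869, 0.596 and 0.341) and with that covariate (0.45), within 1.72e-10 to 0.596 over 21 settings. Of 19 p53 targets and apoptosis genes, 13 had negative differences, with a median of -0.21 (camera adjusted p = 0.00587, and adjusted p = 0.844 with an estimated correlation). The most abundant p53 list members, Aen and Bax, differed by 0.44 (SE 0.29) and 0.04 (SE 0.26). The p53 median was 0.00 without WT 2 and with the file-name number as a block, and -0.43 and -0.32 without WT 3 and WT 4. It was -0.12, -0.47 and -0.11 without Lck-/- 1, Lck-/- 2 and Lck-/- 3, and -0.42 with the median as reference. The call was lost without WT 2 or Lck-/- 1 (adjusted p = 0.0899 and 0.0752), without both doubted arrays (0.0561) and with the file-name number as a block (0.0852), within 0.000344 to 0.0899 over 21 settings. No member of either list passed over all genes or adjusted over the list alone.

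Apart from cholesterol synthesis, the metabolic lists and the stress list were not called, and no member passed over all genes or adjusted over the list alone. Of 21 glycolysis genes, 19 had positive differences, with a median of 0.23 (camera adjusted p = 0.0601), and Gapdh and Aldoa differed by 0.04 (SE 0.17) and 0.19 (SE 0.15). The glycolysis list was called in 7 of 21 settings (adjusted p from 1.24e-05 to 0.66), among them without WT 3 (0.00135), Lck-/- 2 (0.000374) or Lck-/- 3 (0.029) and with the NK marker mean as a covariate (1.24e-05). Its median was 0.00 without Lck-/- 1 (adjusted p = 0.66), 0.15 without WT 2, -0.03 with both doubted arrays out and 0.03 with the median as reference. Its mean relative to WT was 0.79 on the array labelled Lck-/- 1 and -0.15 and 0.06 on Lck-/- 2 and Lck-/- 3. Median differences were 0.07 for 30 ribosome biogenesis genes (camera adjusted p = 0.561) and 0.06 for 21 genes of the unfolded protein and stress response (0.93). They were 0.06 for 19 genes of amino acid, one-carbon and polyamine metabolism and 0.05 for 32 respiratory chain genes, and for both of these camera gave the opposite direction (adjusted p = 0.889 for each). With the median as reference these last 4 medians were -0.13, -0.15, -0.14 and -0.16. Leaving out 1 array moved them within -0.02 (WT 3) to 0.12 (WT 4), -0.07 (Lck-/- 1) to 0.10 (WT 2 or WT 4), -0.06 (Lck-/- 1) to 0.16 (Lck-/- 3) and -0.05 (Lck-/- 1) to 0.09 (Lck-/- 3). Examples were the nucleolar genes Npm1, at 0.11 (SE 0.16), and Ncl, at 0.13 (SE 0.17), and the stress genes Atf4, at 0.10 (SE 0.19), and Hspa5, at 0.09 (SE 0.14). The biosynthetic genes Srm and Phgdh differed by 0.25 (SE 0.23) and -0.05 (SE 0.13), and the respiratory genes Atp5b and Uqcrq by 0.10 (SE 0.17) and -0.02 (SE 0.16).

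Markers of other cell types apart from NK cells were not called, and no member passed over all genes or adjusted over the list alone. Median differences were 0.39 for 17 myeloid and dendritic markers (camera adjusted p = 0.435), 0.52 for 4 B cell markers (0.0743), 0.24 for 7 stromal and endothelial markers (0.665) and 0.25 for 6 erythroid and platelet markers (0.665). In the deposited table these medians were 0.15, 0.11, 0.00 and -0.01, and with the NK marker mean as a covariate 0.01, 0.26, 0.16 and -0.07. The myeloid median was 0.19 without WT 1 and 0.25 without Lck-/- 2. The stromal median was 0.06 without Lck-/- 3, 0.09 without WT 3, 0.14 without WT 1 and 0.15 without WT 4 or Lck-/- 2. The erythroid and platelet median was 0.82 without WT 4, 0.50 without Lck-/- 1, 0.10 without WT 1, 0.04 without WT 3 and -0.14 without Lck-/- 2. The myeloid list was called without WT 2 or Lck-/- 1 (adjusted p = 0.0382 and 0.0318) and with the file-name number as a block (0.0198, the lowest of 21 settings, up to 0.992). The B cell list was called without Lck-/- 3 (0.0399, the lowest of 21 settings, up to 0.348). The most abundant myeloid and dendritic members, Siglech and Cst3, differed by 0.22 (SE 0.21) and 0.33 (SE 0.20, with 3 WT values), and the B cell receptor genes Cd79b and Cd79a by 0.53 (SE 0.24) and 0.48 (SE 0.30, with 3 WT values). Siglech read 7.17 to 8.04, above the T cell receptor component Cd3d at 6.88 to 7.34, so its probe may not measure dendritic cells here. On the Rag-/- background stated for these cells, the B cell list likewise may not measure B cells. Kdr and Pecam1, of endothelium, differed by -0.13 (SE 0.24, with 3 WT values) and 0.40 (SE 0.20). Hba-a1, a globin gene, and Pf4, a platelet gene, differed by 0.00 (SE 0.97) and 0.81 (SE 0.93).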

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

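The tests of an exchange, of where called genes lie, of genes near Lck in each split and of the slide row in both splits, the comparison of receptor signalling with mitosis genes, and the split counts for changed genes were chosen after the results were seen, and the others here before. Of 88 sets of 4 WT values checked, 5 held an array far from the other 3, where chance gives about 1 in 20. Gzmb read 4.48 on the array labelled WT 2, against 6.54 to 6.86 on the other WT arrays. Prf1 read 1.44 on WT 1 (others 1.65 to 1.70), Gapdh 9.73 on WT 2 (others 9.37 to 9.43), Atp5b 8.85 on WT 4 (others 8.97 to 8.99) and Idi2 -2.55 on WT 3 (others -2.19 to -2.12).

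The labelled grouping was set against all 35 splits of the 7 arrays into 4 and 3. It gave 0 calls and 0 calls of at least 2-fold. All 35 splits reach a count of 0 by construction, so these counts say nothing about chance. The highest other splits gave 79 and 75. As many as 9 lists were called by 7 of the 35 splits, the labelled one included, with 13 as the highest other, so chance cannot be excluded there. A pair of splits called many genes while the labelled one called none, which points to structure among the samples or the arrays other than the labels.

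By adjusted calls the larger, with 79 genes, Lck among them, set apart the arrays labelled WT 4, Lck-/- 2 and Lck-/- 3, the same 3 that had the low Lck signal; at an unadjusted p under 0.05 its 1822 genes came after 2311 for the other of the pair and 1889 with WT 1, WT 3 and Lck-/- 1 apart. The row of the arrays on the slide is argued against as the whole cause, since 59 genes were called with the row as a block, and so is a segment around Lck from another strain carried with the knockout under right labels, since tested genes within 20 Mb of Lck had an unadjusted p under 0.05 at 0.71 times the share of other genes in the labelled split, against 2.23 times in this one. Of the 77 other called genes with a position, 16 lay within 20 Mb of Lck on chromosome 4, or 20.8% against 2.8% of the other tested genes (one-sided Fisher's exact test, p = 5.68e-10), so a segment may account for part of the split, but one carried with the knockout would do so only if the labels of WT 4 and Lck-/- 1 are wrong. An exchange of the samples labelled WT replicate 4 and Lck-/- replicate 1, first considered because of the Lck signal and the 79 calls, is a candidate explanation that includes such a segment: only 1 of the 35 splits, the exchanged one itself, reached the ratio of 2.23 (next 1.98), or 2.05 (next 1.72) without the genes called in any split. A segment shared by these arrays for another reason and a biological difference between animals stay open, and Timd2, Cd200, Eomes and Bcl2, picked because they follow the labels, exclude none of these.

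The other split set the arrays labelled WT 3, Lck-/- 1 and Lck-/- 3 apart, which lie side by side on the slide in row 1, columns 1 to 3, with 63 genes called, 62 of them higher there. None of the 79 genes was among them, and with the slide row as a block, which leaves WT 2 as the only array to compare with in that row, their median difference in size was 2.19 (median SE 0.33) against 2.23 (0.22) without it, so the 0 calls made then came with a larger error and not with a smaller difference. Of the 63 genes, 49.2% had a value marked as an outlier by the scanner software on at least 1 of these arrays, against 5.2% of the other genes (one-sided Fisher's exact test, p = 4.76e-23), so spot defects that escaped this marking are a candidate cause, the marked values themselves having been left out. Leaving them out left some genes with 1 value on the 3 arrays, such as Elane, read there only on Lck-/- 3. Spread among the 3 arrays then does not count against a call, so part of this enrichment may come from the missing values. Genes such as Hoxc10, at -6.43 to -5.93 on the other arrays, may have passed the background filter only through these 3, which favours genes higher there. The test of whether their spots lay closer together than random tested spots did not pass (permutation p = 0.181) and leaves a damaged patch open. No biological explanation was tested, since the design names none for these arrays.

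The lower G2 and mitosis genes on the arrays labelled Lck-/- had a median reached in size by 6 of the 35 splits, the labelled one included, so chance cannot be excluded; the labelled median was -1.04 and the largest other, in size, 1.18. A lower share of T cells as the whole cause is argued against, since the receptor signalling genes had a median difference of 0.1 and a lower quartile of -0.04, above the upper quartile of -0.89 of the mitosis genes. With the median as reference the medians of these lists were -0.10 and -1.25. The receptor signalling list is not limited to genes particular to T cells, and NK markers were higher, so a partial replacement of T cells by NK cells was not tested by it. A slower cycle without Lck stays open and untested, and doxycycline history, given only for the Lck-/- samples, cannot be told apart from it.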

How the results depend on the processing

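The 2 alternatives that left out both doubted arrays or took the NK marker mean as a covariate were chosen after the data were seen. Leaving out the doubted arrays selects on their signal, so the calls, medians and Lck difference it gave are no independent check. Under 12 planned settings, and with the NK covariate, the limma count of changed genes was 0 except for 1 gene, also at least 2-fold, with the number in the file names as a block (Tshb). The block by title number gave 0 calls (1681 genes at an unadjusted p under 0.05) and 10 lists. For title numbers 1 to 3 the deviations of paired arrays correlated at 0.09, 0.05 and -0.02. The arrays labelled WT 1 and WT 2 correlated best with their own number, and the others with another. Unadjusted counts were 1175 with quantile normalization, 1186 with normexp, 1008 with median centring, 1291 with the deposited table and 727 with the NK covariate. Leaving out each array gave 0 to 1 calls (the 1, without WT 1, was Xist), 0 to 1 of at least 2-fold, 7 to 10 lists and an Lck difference of -0.93 to -0.01. With both doubted arrays out, 56 genes were called, 56 of them at least 2-fold, and the Lck difference was -1.29. Simulated data gave calls at this number of arrays, and the cause of the low count was not tested. Of the 9 lists, 0 were called with an estimated correlation and 0 by fry's directional test, while its mixed test called 1, the feedback regulators. Estimated correlations of the 9 lists ran from 0.1 (receptors) to 0.92 (G2 and mitosis), all above the preset 0.01. Camera p-values at the preset are therefore likely too small, also over the 21 settings. The labelled median of G2 and mitosis was reached in size by 6 of the 35 splits, the labelled one included. Counted in the same way, it was 7 each for NK markers, receptors and replication, 9 for interferon and 11 for cholesterol synthesis. For cytotoxic genes it was 15, for feedback regulators 16 and for p53 targets 19. Chance cannot be excluded for any of these lists. With the NK covariate 5 lists were called, 4 of the 9 among them, and the NK list itself turned direction in the test (median 0.07), as its own mean was removed. Of the other 13 lists, 6 were called under at least 1 alternative. G2 and mitosis kept its call under all 21 settings that kept camera's preset correlation, with medians from -1.57 to -0.59. No gene passed the threshold in the main setting, so the next count was nearly fixed in advance and does not measure how stable the differences are. Of 1445 values of named genes under alternatives, 1443 kept their side of the threshold with no tested change of direction. Of these, 118 had the other sign with both confidence intervals spanning 0. Among the latter under other scalings were small differences of Gapdh, Aldoa, Ncl, Npm1, Mcm3, Cd3d, Cd69, Il7r, Prf1, Tbx21, Bax, Atf4, Hspa5 and Atp5b. Of the other values, Hba-a1 turned to -1.48 with the NK covariate and Eomes passed the threshold with both doubted arrays out, and the cause was not tested. The Lck difference was 0.34 with the NK covariate. The array carries 1 Lck probe, so a second could not be tried. Dim probes limit the smallest measurable signal: Timd2 has only a bound.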

Other observations

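The values of this paragraph belong to no planned comparison, and the genes were chosen after their values were seen. Genes linked to the sex chromosomes differed between arrays of 1 group, and Xist in part between the groups. Xist, transcribed from the inactive X chromosome, read 1.43 on the array labelled WT 1, -6.43, -7.31 and -6.38 on WT 2 to WT 4, and 0.51, -0.29 and 1.04 on Lck-/- 1 to Lck-/- 3. The Y-linked Eif2s3y read -6.31 on WT 1 and -6.82 on Lck-/- 3, and 2.54 to 3.32 on the other 5 arrays, so the arrays labelled Lck-/- 1 and Lck-/- 2 had high signal for both genes. Xist was well above background on all 3 arrays labelled Lck-/- and on 1 labelled WT, a difference of 5.09 (SE 1.95, limma adjusted p = 0.685). The sex of the animals may therefore differ in part with the labels. Sex was in no model and may add to any difference between the groups. Neither gene was weighed in the test of an exchange. That exchange would put Lck-/- 1 and Lck-/- 2, alike in having signal for both genes, in different groups. Whether these samples held cells of more than 1 animal was not tested.

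Among myeloid markers, the calprotectin genes S100a8 and S100a9 went against most of their list, with differences of -2.27 (SE 0.80) and -2.76 (SE 0.81), limma adjusted p = 0.664 and 0.637. S100a8 was well above background on 4 arrays labelled WT and 1 labelled Lck-/-, and S100a9 on 4 and 2, so both differences rest in part on values not well above background. Il22, a cytokine of type 17 responses, was well above background on all 7 arrays and differed by 2.13 (SE 0.81), and did not pass adjusted over the list alone.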
